A study of Homo sapiens with 6 samples.

How the data were processed

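MicroRNAs (miRNAs), short RNAs that repress target mRNAs, were measured in 6 primary human dermal fibroblast cultures. Per the labels, 3 cultures were grown from biopsies of diabetic foot ulcers (ulcer) and 3 from foot skin of people without diabetes (nondiabetic); the dermis was minced and the fibroblasts were grown out of it. The labels disagree on the passage at which RNA was taken: the series description gives passage 1 or 2, and the sample labels give passage 4. Per the labels, 100 ng of total RNA went into each NanoString nCounter miRNA assay, which hybridises fluorescent barcodes to molecules and counts the barcodes without amplification. The panel as analysed held 800 miRNA probes, 6 positive and 6 negative control probes, 5 spike-in probes and 5 probes for the mRNAs ACTB, B2M, GAPDH, RPL19 and RPLP0, called control genes here.

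Per the labels, the authors processed the data with nSolver 2.0 and normalized to the control genes in the assay; other steps are not given in the sources used here. The deposited counts are whole numbers of molecules per probe before normalization, per the file headers. The deposited normalized signal was set against the counts to find how it was made: in each culture it equalled the count minus the mean plus 2 SD of the negative control probes, floored at 1, times 1 factor that brought the control genes to a common geometric mean, and floored at 1 again. The factor varied by at most 0.0381% over the 50 probes used to find it. Those factors ran from 0.543 in ulcer culture 1 to 2.07 in nondiabetic culture 2. The value table of the series held the same signal with no difference. The deposited score per miRNA is a signed fold, per the file headers for ulcer over nondiabetic, in which a ratio under 1 is written as minus its reciprocal; it was within 0.285% of the ratio of the geometric means of the deposited normalized signal for all 800 miRNAs. Computed from the counts by all these steps, it was matched within 1% for 798 of the 800 and for 75 of the 77 miRNAs kept. Columns were assigned to cultures by name. Replicate numbers were given in accession order within a group and pair no cultures. All per-sample columns were assigned, so 0 were left out.

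Differences were computed from the raw counts with edgeR 4.0.16 in R 4.3.3. A miRNA was detected in a culture when its count was above that culture's mean plus 2 SD of the 6 negative control probes, called the bound, and was kept when detected in at least 3 of the 6 cultures. Control probes, spike-ins and control genes stayed out of library sizes and tests. CPM is the count relative to the TMM-scaled library size of a culture. Library sizes were scaled by TMM, and the quasi-likelihood F test compared the groups with no covariate. P-values were adjusted by Benjamini-Hochberg over the miRNAs kept, with a threshold of 0.05. The standard error (SE) is the size of the log2 fold change divided by the square root of F, and intervals are at 95%. The labels do not say whether the cultures of a group come from separate donors, so the p-values measure only the spread between these cultures. Totals of single cultures were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 against 3.

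Before the data were examined, 24 lists of miRNAs were fixed: fibrosis-associated, collagen-repressing, senescence- or p53-associated, miR-17~92 and paralogs, let-7 family, 14q32 cluster, C19MC cluster, miRNAs of the HOX clusters, wound healing and diabetes, miR-232724, miR-30, miR-181 and miR-15 with miR-107 families, inflammation, hypoxia, markers of keratinocytes, endothelium, leukocytes, smooth muscle, skeletal muscle, neurons, melanocytes and hepatocytes, and viral miRNAs. Lists with at least 5 miRNAs kept were tested with camera at a preset correlation of 0.01, adjusted over the 9 lists so tested; camera with an estimated correlation and fry, both in limma 3.58.1, stand beside it. A probe that reads 2 miRNAs counts once, and 3 of the kept probes are of that kind; the let-7 members differ by few bases, so their probes may share signal.

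The miRNAs named were set by a rule fixed at the same time. In each direction it takes the 12 with the largest change among those that pass the threshold with no overlap between groups, and, where fewer than 10 pass, the smallest unadjusted p up to 10, named as not passing. It adds miR-21-5p, miR-34a-5p and miR-145-5p, which the study's publication is remembered to follow up, up to 4 kept members of each list by smallest p, and every kept member of a list with fewer than 5 kept. This gave 43 miRNAs. Others named are abundant miRNAs, marker miRNAs or miRNAs chosen after their values were seen, as stated where they appear.

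The test was checked on simulated counts for the 77 miRNAs kept, with 20 of them changed in each of 20 sets and dispersions from the fitted trend. It recovered 13.8% of those changed 2-fold, 92.8% of those changed 4-fold and 100% of those changed 8-fold, with 0 false calls per set where none was changed and 1.2 where 20 were changed 4-fold. With tagwise dispersions it recovered 11%, 91% and 98.5%. These shares do not carry over to miRNAs listed at a count of 1 in some cultures. In the real data miR-143-3p, 10.8-fold higher in ulcer cultures, and miR-21-5p, 5.10-fold higher, did not pass in edgeR (adjusted p = 0.951 each). For such miRNAs the absence of a call does not exclude a large change. For 9 miRNAs simulated as independent of each other, camera at its preset correlation gave an unadjusted p under 0.05 in 5% of 100 sets without a shift, in 73% with a log2 shift of 0.5 and in 100% with a log2 shift of 1.

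Alternatives fixed beforehand were the DESeq2 1.42.0 Wald test (local dispersion fit), DESeq2 size factors in edgeR, scaling to the control genes, to the positive controls, to the 100 miRNAs of highest mean and to the total count, no filter, detection in all 6 cultures, a mean count of at least 100, subtraction of the bound, limma with voom, the robust form of the edgeR test, limma on log2 of the authors' normalized signal plus 1, leaving out the 5 most abundant miRNAs, and leaving out each culture in turn. Chosen after the data were seen were raising counts under the bound to it and leaving out miR-21-5p and miR-143-3p. Also chosen then, where a setting moved the median log2 fold change of all miRNAs by over 0.1, changes of single miRNAs under it are given relative to that shift, except where values without it are named as such.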

Results

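The series compares the miRNAs of fibroblasts grown from diabetic foot ulcers with those of fibroblasts from nondiabetic foot skin, 3 cultures each. Total miRNA counts were 220934, 146935 and 122844 in ulcer cultures 1 to 3 and 102917, 52057 and 97773 in nondiabetic cultures 1 to 3. A count above a bound of 79.0 to 140 was needed for detection, depending on the culture. Of 800 miRNAs, 77 were detected in at least 3 cultures and kept, 50 of them in all 6 cultures, and 695 were detected in none. Intervals for shares of counts cover counting error only.

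The 5 most abundant miRNAs made up 42.8 to 56.3% of the total count of a culture. miR-125b-5p made up 25.3% ± 6.81 (SD, n = 6) of the TMM-scaled counts of the kept miRNAs, let-7a-5p 11.2% ± 2.45, let-7b-5p 9.31% ± 2.95, miR-29b-3p, a repressor of collagen mRNAs, 7.13% ± 1.75, and miR-100-5p 4.71% ± 1.63. The probe shared by miR-199a-3p and miR-199b-3p, miRNAs typical of mesenchymal cells, had 4.18% ± 0.211. The share of miR-125b-5p in the total count ran from 17.6% (exact binomial 95% interval 17.3 to 17.8) in nondiabetic culture 1 to 26.8% (26.6 to 26.97) in ulcer culture 1. Of the markers listed for smooth muscle or pericytes, miR-145-5p was above the bound in all 6 cultures, with counts of 302 to 2448, miR-143-3p was above it in the 3 ulcer cultures only, and miR-28-5p in none. Markers of keratinocytes, endothelium, leukocytes, skeletal muscle, neurons and hepatocytes stayed under the bound in every culture. The highest count was 25 among 7 keratinocyte markers such as miR-203 and miR-205-5p, 41 for endothelial miR-126-3p and 64 among 6 leukocyte and red cell markers. It was 38 among 6 skeletal muscle markers, 67 among 5 neural markers and 18 for the hepatocyte miRNA miR-122-5p. The melanocyte marker miR-204-5p passed the bound in 2 cultures, with counts of 129 in ulcer culture 1 and 156 in nondiabetic culture 1, while miR-211-5p did not pass it in any. Of the miR-30 family and of the placental C19MC cluster, 0 members were kept, and their highest counts were 100 and 50.

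The comparison asks which miRNAs differ between fibroblasts of diabetic foot ulcers and those of nondiabetic foot skin. No group had diabetes without an ulcer or a wound without diabetes, so diabetes and ulceration cannot be told apart. miR-143-3p, which with miR-145 promotes the contractile state of smooth muscle, had a mean CPM (TMM-scaled count relative to the library size) of 3858 ± 1864 in ulcer cultures and 349 ± 576 in nondiabetic cultures (SD, n = 3 each). This is a log2 fold change of 3.43 (SE 1.27, 95% interval 0.44 to 6.42). Its raw counts were 465, 392 and 719 against 1, 1 and 75, so it was above the bound in no nondiabetic culture as listed. With those 3 at their bound it was 2.65-fold higher in ulcer cultures. This is a lower limit only if the counts of 1 are as measured, which is not known. miR-21-5p, an abundant miRNA raised in many fibrotic tissues, had 12591 ± 1607 against 2441 ± 4196 CPM, a log2 fold change of 2.35 (SE 1.70, interval −1.66 to 6.36), from raw counts of 2382, 1794 and 1300 against 775, 1 and 1. miR-374a-5p was the other miRNA with all ulcer values above all nondiabetic values, at a log2 fold change of 0.58 (SE 0.29). None of these passed the threshold. EdgeR called 0 of 77 miRNAs, with a smallest adjusted p = 0.951, and 2 miRNAs, miR-143-3p and miR-302d-3p, had an unadjusted p under 0.05. DESeq2 and limma with voom also called 0, with 6 and 3 at that unadjusted level.

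Among the other miRNAs with the smallest p and higher values in ulcer cultures, the p53 target miR-34a-5p had a log2 fold change of 0.59 (SE 0.33), miR-132-3p 0.52 (SE 0.34), miR-450a-5p 0.53 (SE 0.36), miR-140-5p 0.44 (SE 0.30), miR-503 0.80 (SE 0.60), miR-181a-5p 0.40 (SE 0.31) and miR-99a-5p 0.33 (SE 0.26). miR-145-5p, made from the same precursor as miR-143, was detected in all 6 cultures at 15848 ± 3910 against 11121 ± 8674 CPM (SD, n = 3 each), a log2 fold change of 0.51 (SE 0.54, interval −0.76 to 1.79), and 0.17 to 1.29 with 1 culture left out. Leaving out 1 culture likewise gave 0.12 to 0.72 for miR-132-3p, 0.27 to 0.87 for miR-450a-5p, 0.21 to 0.65 for miR-140-5p, 0.10 to 0.57 for miR-181a-5p and 0.19 to 0.56 for miR-99a-5p. miR-503 ran from −0.051 without ulcer culture 3 to 1.30 without ulcer culture 2. On the lower side, miR-4454 had a log2 fold change of −2.09 (SE 0.92), with 6517 ± 5355 against 27853 ± 25871 CPM, and −3.01 to −1.09 with 1 culture left out. miR-720, a name since assigned to tRNA fragments, had −1.08 (SE 0.61). miR-378e had −0.93 (SE 0.44) and miR-302d-3p −0.87 (SE 0.32). The counts of miR-302d-3p lay between 0.939 and 1.29 times the bound in the 6 cultures. Smaller differences were −0.50 (SE 0.30) for miR-26a-5p, −0.51 (SE 0.39) for miR-31-5p, −0.44 (SE 0.34) for miR-29c-3p, −0.27 (SE 0.22) for miR-574-5p, −0.30 (SE 0.26) for miR-23a-3p and −0.36 (SE 0.34) for miR-411-5p. With 1 culture left out, miR-26a-5p ran from −0.79 to −0.18, miR-31-5p from −0.91 to −0.28 and miR-29c-3p from −0.79 to −0.12. The groups did not overlap for 5 miRNAs, 3 higher and 2 lower, where chance gives 10%, or 7.7 of 77.

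**Figure D1:**
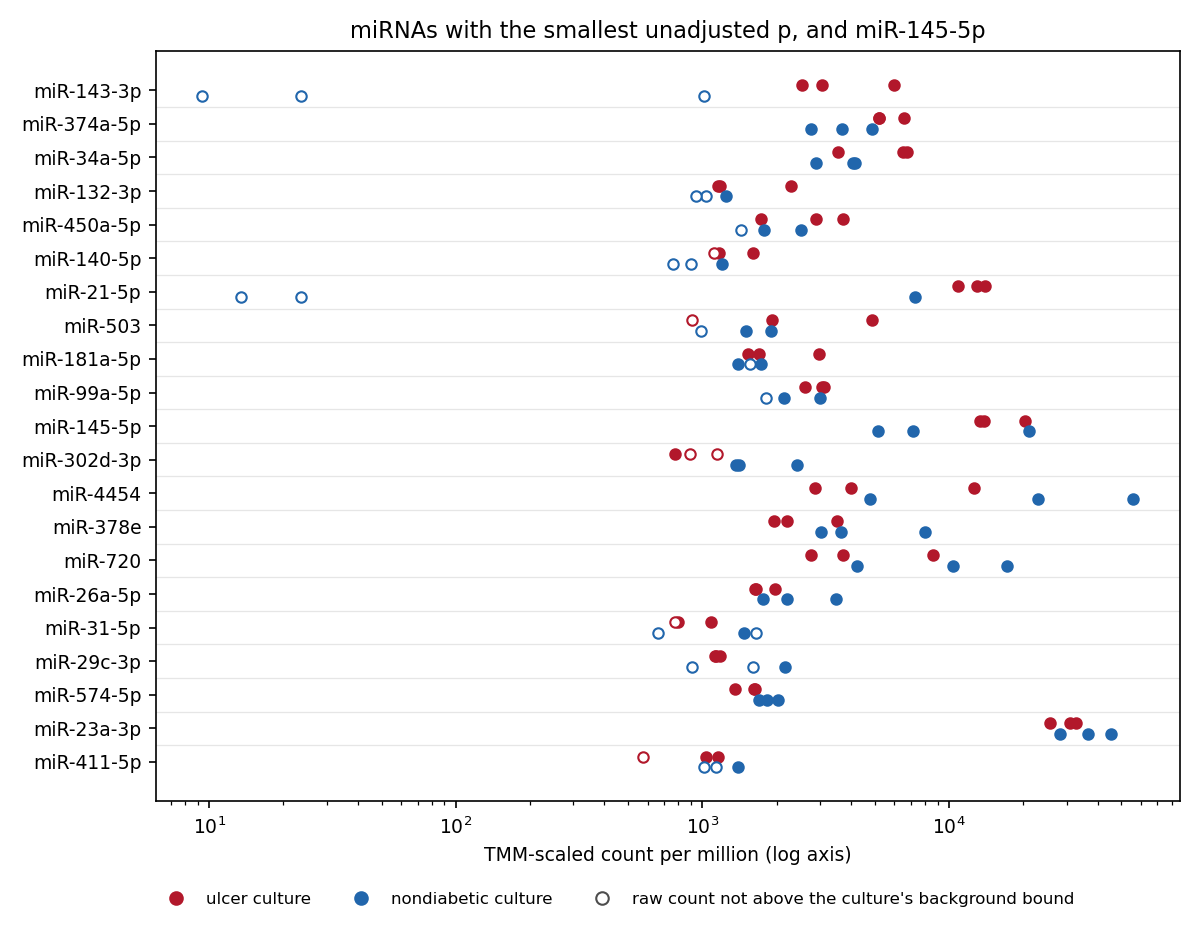
Each point is 1 culture's TMM-scaled CPM (log axis) for the miRNAs with the smallest unadjusted p in each direction and miR-145-5p, red for ulcer and blue for nondiabetic, open where the raw count was not above that culture's bound. Ulcer and nondiabetic points separate for miR-143-3p, miR-374a-5p and miR-21-5p on the higher side and for miR-302d-3p and miR-574-5p on the lower side, and 0 of the miRNAs passed an adjusted p of 0.05.

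The median SE was 0.325 log2 units, and for 39 of the 77 miRNAs the 95% interval excluded a change of 2-fold or more in either direction under TMM. That count holds only relative to the TMM scale and for counts with background left in. Some of the 39 were not above the bound in every culture, and for these a 2-fold change is not excluded. An example is miR-107, not above the bound in 3 cultures, with an interval of −0.80 to 0.39. With the bound subtracted, its log2 fold change relative to the shift of the median was 1.82. The median log2 fold change was 0.053 under TMM, but 0.62 when scaled to the control genes or to the positive controls. miR-21-5p passed with nondiabetic culture 1 left out and miR-143-3p with nondiabetic culture 3 left out, but in each case both remaining nondiabetic counts were 1, so that no fold or p can be read from these fits. With all counts under the bound raised to it, edgeR called 0 of 77 (smallest adjusted p = 0.192), and the log2 fold changes were 1.54 for miR-143-3p and 1.88 for miR-21-5p.

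The 9 kept miRNAs of the fibrosis-associated list had a median log2 fold change of 0.51 and a mean of 0.90, with 8 positive and 1 negative. The median was the same, and the mean 0.67, with miR-143-3p at its bound. The largest were miR-143-3p, miR-21-5p, miR-503 and miR-34a-5p, while the probe for miR-199a-3p and miR-199b-3p had 0.068 (SE 0.20), miR-199a-5p 0.26 (SE 0.33) and miR-214-3p −0.12 (SE 0.24). By camera the list was higher in ulcer cultures (adjusted p = 0.00202), and 0 members passed over all miRNAs or adjusted over the list alone. With an estimated correlation camera called 0 lists, this one at adjusted p = 0.144. The correlation estimated for this list was −0.045, under the preset 0.01, so a higher correlation of its members does not account for the larger p. miR-143-3p and miR-145-5p, members of this list, are also the kept markers of smooth muscle or pericytes. Their median was 1.97 with counts as listed, from 3.43 for miR-143-3p, above the bound in no nondiabetic culture, and 0.51 for miR-145-5p. The list therefore does not separate a fibrosis-associated difference from one in those markers. Fry, whose p tests whether a list moves on balance 1 way and whose mixed p tests movement in either direction, gave adjusted p = 0.111 and adjusted p = 0.0799; neither compares the list with other miRNAs. The camera call was also lost when detection in all 6 cultures was required (adjusted p = 0.148), without ulcer culture 3 (adjusted p = 0.0580) and without miR-21-5p and miR-143-3p (adjusted p = 0.209). In all it was lost under 4 alternatives and kept under 11. Camera gave adjusted p = 0.000231 with counts raised to the bound, 8.16e-05 scaled to the control genes and 0.0436 scaled to the positive controls. Because miR-21-5p, miR-34a-5p and miR-145-5p were remembered from the study's publication, the list is not independent evidence of its direction.

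No other list passed. The 5 collagen-repressing miRNAs had a median log2 fold change of −0.24 (camera, adjusted p = 0.270), with miR-26a-5p and miR-29c-3p lowest, miR-196a-5p at −0.24 (SE 0.27) and the abundant miR-29b-3p at −0.077 (SE 0.32). The 15 miRNAs of wound healing and diabetes had a median of 0.14, 12 positive and 3 negative (adjusted p = 0.270), and the 6 senescence- or p53-associated miRNAs a median of 0.20 (adjusted p = 0.357). Among the latter were miR-376a-3p at 0.22 (SE 0.36) and miR-107 at −0.21 (SE 0.25). The 5 inflammation miRNAs had a median of 0.086 (adjusted p = 0.357), with miR-222-3p at 0.086 (SE 0.22), and passed without nondiabetic culture 1 (adjusted p = 0.0134), where miR-21-5p, 1 of the 5, had a count of 1 in both remaining nondiabetic cultures. The proliferation-associated miR-17~92 miRNAs and paralogs had a median of 0.20 (adjusted p = 0.458). Their values included miR-93-5p at 0.20 (SE 0.32), miR-19b-3p at 0.23 (SE 0.52), the probe for miR-20a-5p and miR-20b-5p at 0.25 (SE 0.49) and that for miR-106a-5p and miR-17-5p at 0.15 (SE 0.38). The family of miR-15 and miR-107 had a median of 0.17 (adjusted p = 0.562), with miR-15a-5p at 0.28 (SE 0.44) and miR-16-5p at 0.17 (SE 0.27).

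The 9 let-7 miRNAs, known for repressing growth-promoting mRNAs, had 4 positive and 5 negative log2 fold changes with a median of −0.0031 (adjusted p = 0.931), from −0.20 (SE 0.34) for let-7b-5p to 0.26 (SE 0.29) for let-7i-5p, with let-7d-5p at 0.15 (SE 0.26) and let-7f-5p at −0.18 (SE 0.32). Camera gave the list a downward and fry an upward direction, and scaling to the control genes or to the positive controls turned the camera direction upward. The 12 kept miRNAs of the imprinted 14q32 cluster were split 6 to 6 with a median of −0.025 (adjusted p = 0.446), including miR-382-5p at −0.31 (SE 0.41) and miR-299-5p at −0.26 (SE 0.33). This list passed as lower without ulcer culture 2 (adjusted p = 0.0157) and turned upward without ulcer culture 3 (adjusted p = 0.142). Lists with too few kept for a test were the HOX cluster miRNAs miR-196a-5p and miR-196b-5p (−0.054, SE 0.26), the miR-232724 miRNAs, with miR-24-3p at 0.13 (SE 0.20), miR-23b-3p at 0.13 (SE 0.26) and miR-27b-3p at 0.18 (SE 0.24) beside miR-23a-3p, and the miR-181 family with miR-181a-5p alone. The 4 hypoxia miRNAs kept, miR-21-5p, miR-26a-5p, miR-107 and miR-199a-5p, had 2 positive and 2 negative values, and the smooth muscle markers were miR-143-3p and miR-145-5p. The panel analysed held 0 viral probes.

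**Figure D2:**
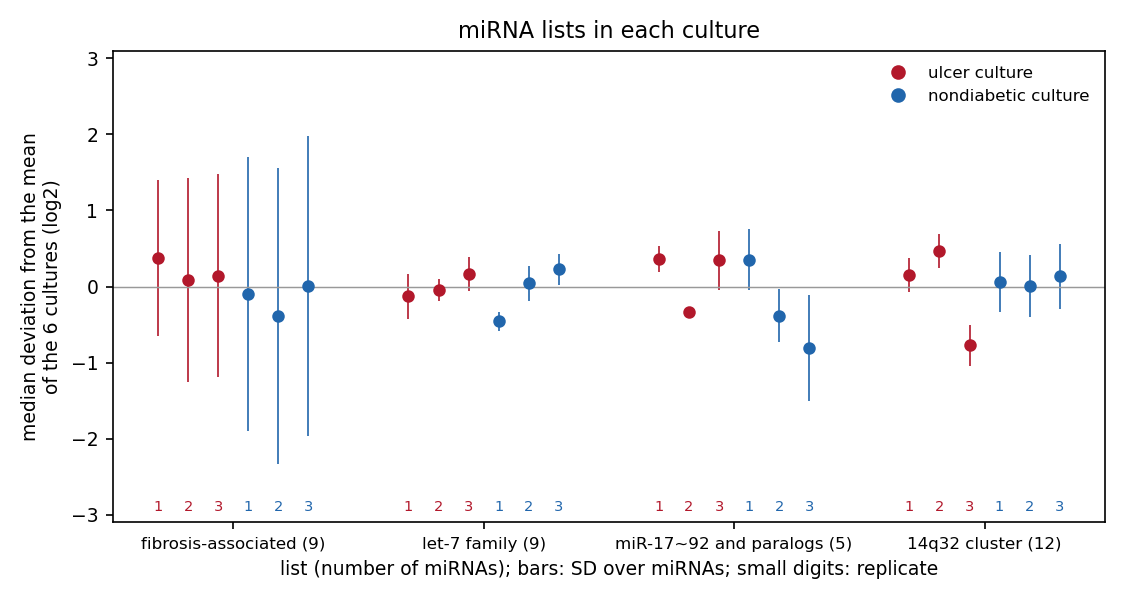
Points give, for each culture (red ulcer, blue nondiabetic, small digits the replicate), the median log2 deviation of a list's miRNAs from their mean over the 6 cultures, and bars the SD over those miRNAs. The 14q32 cluster was lowest in ulcer culture 3, at −0.77, where 9 of its 12 miRNAs were not above the bound, and the let-7 family lowest in nondiabetic culture 1, at −0.45.

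Detection and totals were compared between the groups, since they set the scale of all differences. A mean of 81.3 ± 20.5 miRNAs was detected in ulcer cultures and 66 ± 12.5 in nondiabetic cultures (SD, n = 3 each; exact permutation p = 0.5). The total miRNA count was 1.97-fold higher in ulcer cultures, with every ulcer culture above every nondiabetic one (exact permutation p = 0.1, the smallest possible). Relative to the positive control probes the kept miRNAs were 1.53-fold higher (exact permutation p = 0.1), and relative to the control genes 1.62-fold (exact permutation p = 0.2). The control genes themselves differed 1.28-fold (exact permutation p = 0.6), and the negative control probes 1.31-fold (exact permutation p = 0.1). The positive control probes were also 1.36-fold higher in ulcer cultures (exact permutation p = 0.2). Relative to the positive controls, the negative control probes differed 0.964-fold (exact permutation p = 0.8) and the control genes 0.943-fold (exact permutation p = 0.9). Scaled to the control genes, the median log2 fold change moved from 0.053 to 0.62, a shift of 0.56, with 72 miRNAs higher and 5 lower in place of 42 and 35, and miR-143-3p alone passed in edgeR, with its 2 counts of 1 as listed. Scaled to the positive controls, 73 were higher and 4 lower, 0 passed and 15 had an unadjusted p under 0.05.

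The authors' deposited table of folds, ulcer over nondiabetic, lists miR-143-3p at 282.98 and miR-21-5p at 140.66, followed among the miRNAs kept by 11.23 for miR-132-3p, 9.94 for miR-450a-5p, 9.55 for miR-181a-5p and 9.19 for miR-99a-5p. The authors' deposited table gives 3.13 for miR-145-5p and 3.09 for miR-34a-5p, and its lower values include −9 for miR-302d-3p and −2.53 for miR-4454. It holds 63 miRNAs at 2 or more and 4 at −2 or less, and all 695 miRNAs under the bound in every culture stand at −1.09. Of the 63, 22 were above the bound in all 6 cultures and 41 were under it in at least 1. Among the 77 miRNAs kept, 46 stood at 2 or more in the authors' deposited table, of which 2, miR-143-3p and miR-21-5p, were also at least 2-fold higher under TMM. Scaled to the control genes without subtraction, 10 of the 46 were at least 2-fold higher in the count-based fit, among them miR-145-5p and miR-503. The sign of the authors' deposited fold was that of the TMM fold for 47 of the 77 miRNAs and that of the fold scaled to control genes for 75.

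**Figure D3:**
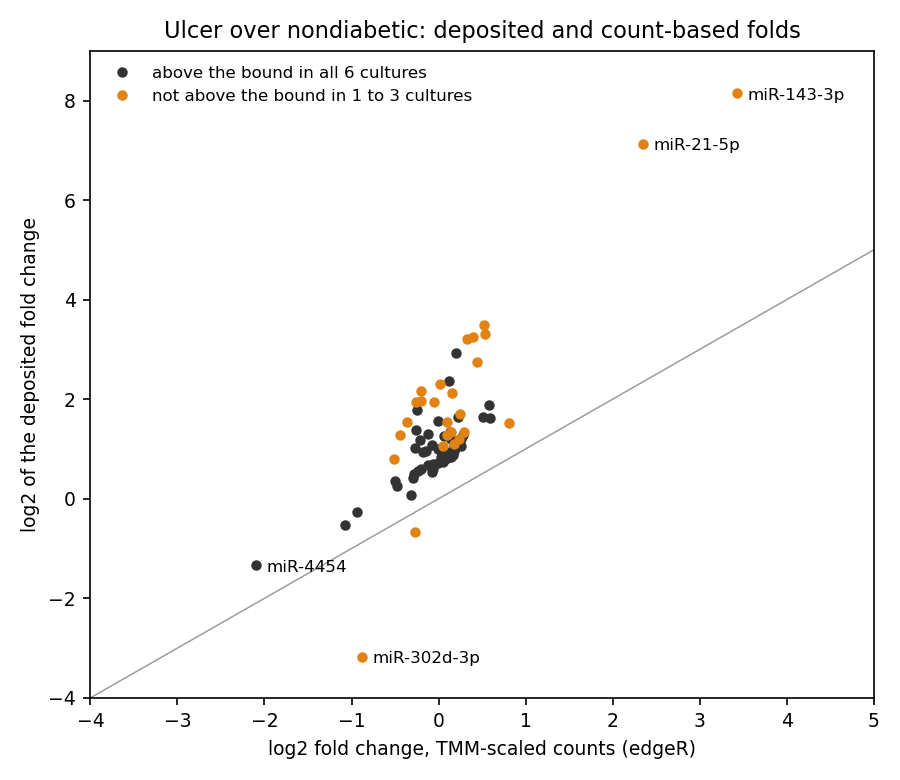
Each point is 1 of the 77 miRNAs kept, with the log2 fold change of TMM-scaled counts (edgeR) on the x axis and log2 of the authors' deposited fold on the y axis, orange where the miRNA was not above the bound in 1 to 3 cultures; the line marks equal values. Most points lie above the line, with miR-143-3p and miR-21-5p at deposited log2 folds of 8.14 and 7.14.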

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

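Chosen after the results were seen were the level at which a miRNA is listed in the next paragraph and every test of the counts of 1 and of the lower probes; the counts of other splits of the cultures were fixed beforehand.

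Outside the 77 miRNAs kept, 28 were above the bound in 1 or 2 cultures, and 27 of these 28 were above it in ulcer culture 1, the culture with the highest total. Singled out by a count at least 2 times the bound in an ulcer culture, with no nondiabetic culture above its own bound, were 4 of them, all in ulcer culture 1, whose bound was 118. The inflammation-linked miR-146a-5p had a count of 296 there, 43 and 41 in ulcer cultures 2 and 3 and at most 100 in a nondiabetic culture. miR-324-5p had 269, then 130 and 48, and at most 108; miR-4286 had 407, then 65 and 46, and at most 112. miR-494 of the 14q32 cluster had 271, then 65 and 24, and at most 92. For miR-146a-5p, miR-4286 and miR-494 ulcer cultures 2 and 3 were thus under the highest nondiabetic count, while miR-324-5p was above the bound in ulcer culture 2 as well.

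miR-143-3p and miR-21-5p, the largest differences with counts as listed, rest on a count of exactly 1 in 2 nondiabetic cultures each. With counts raised to the bound their log2 fold changes were 1.54 and 1.88, smaller in size than −2.02 for miR-4454. Low depth is argued against: at the mean share of the ulcer cultures, the smallest of the 4 counts to be expected was 163. A candidate explanation is that some probes were corrected and floored at 1 before the counts were deposited, since the table holds no 0 but 59 values of 1 among 4800, and 6 probes stand at 1 in all 6 cultures; this says nothing of what the level was. Less of the precursor shared by miR-143 and miR-145 in nondiabetic cultures stays open: with miR-143-3p at its bound, the ratio to miR-145-5p was 2-fold or more under the lowest ulcer ratio in 1 nondiabetic culture only, and in the other two the bound is too high to decide. A true difference between ulcer and nondiabetic cultures, within the fibroblasts or in a share of smooth muscle cells or pericytes, also stays open and was not tested by another assay here.

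The probes with the lowest values in ulcer cultures differed in how far their counts lay above the bound. For miR-302d-3p, background divided by a smaller total in nondiabetic cultures may account for the difference: its count was at most 1.29 times the bound in any culture, and the negative control probes put through the same scaling differed by −0.64 log2 units, against −0.87 for the miRNA. For miR-4454, miR-720 and miR-378e the counts were never under 2.32 times the bound. After subtraction of the bound their log2 fold changes were −2.70 (SE 0.99), −1.55 (SE 0.71) and −1.32 (SE 0.71), larger in size than before. These values do not allow for the shift of the median by 0.13. Subtracting background at the level of the negative control probes thus did not remove the differences. It cannot test background particular to a probe or an effect of the scaling. Scaled to the control genes, without allowing for the shift of the median, the log2 fold changes were −1.77, −0.72 and −0.20, against −0.17 for miR-302d-3p. Leaving out 1 culture gave −3.01 to −1.09 for miR-4454, −1.71 to −0.54 for miR-720 and −1.27 to −0.39 for miR-378e, smallest in size each time without nondiabetic culture 2. None of these 3 passed the threshold in the comparison of the groups, and a difference between ulcer and nondiabetic cultures stays open.

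The 6 cultures can be split 3 against 3 in 10 ways, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 2 miRNAs and the highest other split 7, and 7 of the 10 splits gave as many as the real one. At an adjusted p under 0.05 the real split gave 0 and the highest other 2, so all 10 gave as many. For the fibrosis-associated list the real split had an unadjusted camera p of 0.000224 and the smallest other 0.0183, so 1 of the 10, the real one, gave so small a value.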

How the results depend on the processing

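Raising counts to the bound and leaving out miR-21-5p and miR-143-3p were chosen only after the results were seen, as was the rebuilding of the deposited folds. Depth limits the low miRNAs, since 27 of the 77 kept had at least 1 culture not above its bound. The cause of a change was not tested except where fewer cultures or miRNAs in a setting give it.

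Over 22 alternatives the count of miRNAs past the threshold stayed at 0 under 17. It was 1, miR-143-3p, with control gene scaling and with the bound subtracted, and 2, miR-143-3p and miR-21-5p, with limma on the authors' normalized signal. Leaving out 1 culture gave 0 to 1: miR-21-5p without nondiabetic culture 1 and miR-143-3p without nondiabetic culture 3. All these calls rest on at least 2 nondiabetic values at a floor or under the bound, so their folds and p are not given; with counts raised to the bound 0 passed. The split of miRNAs, 42 higher and 35 lower, was 72 and 5 with control gene scaling and on the authors' signal, 73 and 4 with positive control scaling and, over the same 77, with no filter, 50 and 27 with the bound subtracted, 22 and 28 of 50 with detection in all 6 cultures, and 29 and 48 without ulcer culture 2. At an unadjusted p under 0.05 the count of 2 became 54 of 800 with no filter and 15 with positive control scaling, and 11, 5 and 0 without nondiabetic cultures 3, 1 and 2.

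The fibrosis-associated list, higher in every setting, ended its call with detection in all 6 cultures (adjusted p = 0.148), without miR-21-5p and miR-143-3p (0.209) and with an estimated correlation (0.144); each of these 3 left 0 lists past the threshold. Leaving out 1 culture gave 0.000246 to 0.0580, the latter without ulcer culture 3, and 0 to 2 lists. Counts raised to the bound kept the call of the fibrosis-associated list, at 0.000231. The 14q32 cluster ran from 0.0157 (lower, without ulcer culture 2) to 0.850 and turned higher without ulcer culture 3, at 0.142. The inflammation list, which holds miR-21-5p, passed without nondiabetic culture 1 (0.0134). The let-7 list turned upward at adjusted p = 0.985 with control gene scaling, 0.444 with positive controls, 0.984 with the total count, 0.818 with detection in all 6, 0.622 with counts raised to the bound and 0.856 without miR-21-5p and miR-143-3p, and ran from 0.259 to 0.910 without single cultures, upward in 4 of those 6 fits; it turned upward in 10 alternatives in all. The family of miR-15 and miR-107 ran from 0.234 to 0.919 and turned lower at the latter, without nondiabetic culture 2, and without ulcer culture 3, and the miR-17~92 list turned lower with counts raised to the bound, at 0.480.

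Of 924 log2 fold changes of the 43 named miRNAs under alternatives, 39 turned sign, in 19 miRNAs, and 6 newly passed; counting relative to a shift of the median lowers the first number. Turned values were 0.094 (miR-574-5p), 0.61 (miR-411-5p), 1.82 (miR-107), −0.041 (miR-19b-3p), 1.68 (miR-299-5p), 0.27 (miR-196b-5p) and −0.053 (miR-222-3p) with the bound subtracted, and −0.066 (miR-19b-3p), 0.066 (let-7b-5p) and 0.054 (let-7f-5p) with control gene scaling. On the authors' signal they were 0.24 (miR-411-5p), 0.84 (miR-107), −0.00034 (miR-19b-3p), 0.62 (miR-299-5p), 0.73 (miR-196b-5p), −0.034 (miR-16-5p) and −0.088 (miR-222-3p). With counts raised to the bound they were −0.046 (miR-140-5p), −0.30 (miR-20a-5p and miR-20b-5p), −0.34 (miR-19b-3p) and −0.16 (miR-106a-5p and miR-17-5p), and with voom −0.029 (miR-20a-5p and miR-20b-5p) and −0.061 (miR-19b-3p). Without single cultures the ranges that crossed 0 were −0.47 to 0.11 for let-7b-5p, −0.013 to 0.29 for let-7d-5p, −0.41 to 0.095 for let-7f-5p, −0.20 to 0.43 for miR-106a-5p and miR-17-5p, −0.036 to 0.64 for miR-15a-5p, −0.21 to 0.055 for miR-196b-5p, −0.030 to 0.58 for miR-199a-5p, −0.15 to 1.08 for miR-19b-3p, −0.13 to 0.93 for miR-20a-5p and miR-20b-5p, −0.026 to 0.23 for miR-23b-3p, −0.41 to 0.17 for miR-29b-3p and −0.051 to 1.30 for miR-503. The other named miRNAs kept their sign, but most moved in size: 0.17 to 1.29 for miR-145-5p, 0.12 to 0.72 for miR-132-3p, 0.27 to 0.87 for miR-450a-5p, 0.21 to 0.65 for miR-140-5p, 0.34 to 0.84 for miR-34a-5p, 0.40 to 0.81 for miR-374a-5p, 0.10 to 0.57 for miR-181a-5p and 0.19 to 0.56 for miR-99a-5p. Among the lower ones the ranges were −3.01 to −1.09 for miR-4454, −1.71 to −0.54 for miR-720, −1.27 to −0.39 for miR-378e, −1.10 to −0.57 for miR-302d-3p, −0.79 to −0.18 for miR-26a-5p, −0.91 to −0.28 for miR-31-5p, −0.79 to −0.12 for miR-29c-3p, −0.37 to −0.19 for miR-574-5p, −0.45 to −0.20 for miR-23a-3p and −0.56 to −0.12 for miR-411-5p. Some came close to 0: −0.51 to −0.016 for miR-382-5p, −0.41 to −0.011 for miR-299-5p, 0.0055 to 0.46 for miR-93-5p, 0.043 to 0.49 for miR-376a-3p, 0.022 to 0.38 for miR-16-5p, 0.071 to 0.41 for let-7i-5p, −0.38 to −0.089 for miR-107, −0.46 to −0.070 for miR-196a-5p, 0.032 to 0.17 for miR-222-3p, 0.067 to 0.17 for miR-24-3p and 0.059 to 0.33 for miR-27b-3p.

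The sign of the deposited fold was that of the count-based fold for 47 of 77 miRNAs under TMM and 75 with control gene scaling. Subtraction of the bound with the floor of 1 was tested as the source of the larger deposited folds: a first test, which asked for a median excess over 1 log2 unit in miRNAs with a culture below the bound, was narrowly missed at 0.96 (SD 1.11, n = 27, against 0.15, SD 0.44, n = 50). In the test then chosen, subtraction and floor together with the control gene factors and geometric means rebuilt 97.4% of the 77 deposited folds within 1%. These steps had been found from the deposited signal itself, so the match does not single out subtraction as the source. Ratios of geometric means scaled to the control genes without subtraction already gave log2 folds of 7.23 for miR-21-5p and 6.56 for miR-143-3p. The deposited log2 folds were 7.14 and 8.14. Control gene scaling did not shift all alike, so the differences from TMM folds (SD 0.961) cannot test it.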

Other observations

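The tests of the lists in single cultures were chosen after the values were seen; the test of the correlations was fixed before its result.

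Within the ulcer group the miRNAs of the imprinted 14q32 cluster, expressed from the maternal chromosome, differed between cultures. Their median deviation from the mean of the 6 cultures was −0.77 log2 units (SD over 12 miRNAs 0.27) in ulcer culture 3, where 9 of the 12 had their lowest value, and 0.46 (SD 0.22) in ulcer culture 2, where 5 had their highest. In ulcer culture 3, 9 of the 12 were not above the bound, so their levels there are upper limits at best; with such counts raised to the bound the median was −0.57 (SD 0.32). The other 4 cultures had medians from 0.01 to 0.15. In nondiabetic culture 1 the let-7 family had a median deviation of −0.45 (SD over 9 miRNAs 0.12) and 8 of the 9 had their lowest value.

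A low-count effect on ulcer culture 3 is argued against as the source of its 14q32 values: none of 10000 random lists of 12 kept miRNAs matched on mean expression had a median there as low as −0.77, and with counts raised to the bound none was as low as −0.57. A difference between the cultures in this imprinted cluster is a hypothesis that may merit a closer look, with passage, donor and growth state left untested: the sample labels give the same passage for all 6 cultures, in conflict with the series description, and do not state donor or growth state per culture.

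The ulcer cultures correlated more with each other than the nondiabetic cultures did, with mean Pearson correlations of log2 CPM across the 77 miRNAs, which are not independent replicates, of 0.940 and 0.854. Without miR-21-5p and miR-143-3p the values were 0.942 and 0.928, a difference of 0.0143 in place of 0.0861, and 8 of the 20 trios of cultures correlated as highly as the ulcer trio, in place of 1.

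On the X chromosome MIR450B, MIR450A1, MIR450A2, MIR542, MIR503 and MIR424 are neighbours among the miRNA genes of the GRCh38 annotation used for names. Their kept products miR-450a-5p and miR-503 had log2 fold changes of 0.53 and 0.80 without passing, both highest in ulcer culture 3 at 3732 and 4882 CPM. Without that culture the log2 fold changes were 0.27 and −0.051. miR-424-5p, chosen after its values were seen, was above the bound in ulcer culture 3 alone, at a count of 221 against at most 70 elsewhere.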
